A study of Rattus norvegicus with 12 samples.

How the data were processed

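RNA was measured on 12 arrays, 3 in each of 4 groups of primary rat cortical astrocytes. Per the labels' protocols, total RNA was extracted with Trizol and sense cDNA was fragmented and biotin-labelled for whole-transcript arrays. The deposited table held log2 expression values, 1 per transcript cluster and array, summarised by the authors. The method of background correction, summarisation and normalization is not given in the sources used here, and the log base was inferred from the range of the values, 1.01 to 13.43, with 0 missing. Column medians over the named genes differed by at most 0.083 between arrays. Over all rows they ran from 5.51 in siCon replicate 1 to 5.67 in siCon replicate 2. No further normalization was applied in the main fits, and centring on the medians over all rows was among the alternatives. Per the series text, 4 arrays were re-analysed from an earlier series, and it does not say which.

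The table held 36685 rows. In the probe annotation 18511 rows were paired with exactly 1 gene, 575 with several and 17599 with none. Of the rows with 1 gene, 18394 were matched by Entrez ID to the RefSeq gene table of assembly GRCr8, which changed 0 symbols. Rows with several genes were not named. For the 291 genes with more than 1 row, the row with the highest mean over the arrays was used, which left 18166 genes. Signal over background was judged from 1344 olfactory and vomeronasal receptor genes, whose mean values had a median of 3.30 and a 95th percentile of 5.34. Columns of other samples numbered 0.

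Groups and replicate numbers came from the sample titles. Before the data were examined, the tests, the alternatives, the rule for naming genes and 21 gene lists were fixed. The lists held 414 memberships, of which 365 had a row. They covered interferon signalling, interferon-inducible GTPases, antiviral genes, antigen presentation, chemokines, cytokines and effectors, NF-κB targets and feedback genes, targets of LXR, FXR and PPAR, and cholesterol synthesis. They also covered nuclear receptors and corepressors, immediate-early genes, stress response, cell cycle, ribosomal protein genes and markers of astrocytes, microglia, oligodendrocytes, neurons and meningeal and vascular cells. The labels give the compound only as GW, so no target of it was assumed.

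Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes on 4 group means over all 12 arrays). Genes at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were counted. Lists were tested with fry (directional and mixed) and with camera at a preset correlation of 0.01 and at an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Fry tests whether a list's genes move, and does not compare them with other genes. Members were also counted when adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

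Named genes were chosen by rule in each of 3 comparisons. They were the 10 largest rises and falls among genes that passed and whose groups did not overlap, the genes with the smallest p up to 10 where fewer passed, up to 4 members of each list with the smallest p, and Nr0b2, Irf1, Cxcl10, Ccl2, Nos2, Socs1, Gbp2, Abca1, Srebf1 and Gfap in each; 1 further gene of the rule is not reported here. In the other comparisons only genes named in this way were used. Klf4, Ptpn6 and Ptpn11, and in the closing part Cxcl1, Cxcl2, Ccl3, Ccl4, Nfkbiz, Nr4a1 and Ly86, were named after their values were seen. With 3 against 3 arrays about 10% of genes have groups that do not overlap by chance; 9.3%, 15.3% and 6.47% had none in the 3 comparisons.

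Replicate numbers were checked for pairing before the fits were compared. Deviations from the group mean were correlated between arrays of the same number in different groups. The correlations were 0.63 to 0.77 for number 1, 0.48 to 0.58 for number 2 and 0.43 to 0.55 for number 3. Each was over 0.1, so the numbers were read as paired. The main fits, on group means alone, did not use this pairing. Their counts, SEs and adjusted p ignore it, and only the fits with a block take it into account. The pairing came from number 1: principal component 1 (46.5% of the variance) parted its arrays from the others by 67.4% of the range. The differences between numbers 2 and 3 correlated by only -0.02 to 0.00 between groups. The block of replicate number was therefore computed for each result, and fits without replicate 1 and with number 1 against the others as a batch block were added after the data were seen. A model with separate effects for number 1 tested whether it differed from numbers 2 and 3. It has 1 array per group in number 1, takes the spread only from numbers 2 and 3, and assumes that number 1 varies like them.

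The fits were tested on simulated data with 1 replicate effect per gene and number, taken from the arrays and the same in all groups. Treatment effects that differed in number 1, as on these arrays, were not simulated, so the shares called do not cover that case. In the simulation 67, 67 and 66 of 18166 genes were changed by log2 0.5, 1 and 2 in the comparison of GW under interferon-γ. Without the block, 13.4%, 79.1% and 92.4% of them were called, with 0 false calls. With the block these shares were 56.7%, 94.0% and 98.5%, with 10 false calls, and both made 0 calls in a simulated siRNA comparison without effect. Values expected from shared arrays were taken from 100 simulations with the residual spread of each gene, drawn independently for each gene. Those for the correlations held no replicate effects.

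Alternatives were quantile normalization, centring on array medians, removal of the dimmest 33.3% of genes, the mean of a gene's rows, all rows of the table, eBayes with trend and robust settings, a fixed and a random replicate block, array weights, only the arrays compared, stricter and looser thresholds (at least 1.5-fold; adjusted p under 0.10), and leaving out each array or replicate number.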

Results

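Transcript levels were measured on 12 arrays of cultured rat astrocytes in 4 groups of 3. The cells came from the cerebral cortex of Sprague-Dawley pups 1 day old and had been kept in serum-free medium to remove microglia and meningeal cells. The median level of the microglia markers was still 8.55 to 9.60 on the 12 arrays, against a median of 6.55 for all genes. Changes below therefore cannot be assigned to astrocytes alone. The groups were control siRNA without further treatment (siCon), control siRNA with interferon-γ (siCon_IFNg), control siRNA with interferon-γ and a compound the labels call GW (siCon_IFNg_GW), and SHP siRNA with interferon-γ and GW (siSHP_IFNg_GW). Treatment lasted 3 h. SHP was read as small heterodimer partner, the nuclear receptor encoded by Nr0b2. Values are log2 expression for 18166 genes. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical.

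The arrays numbered 1 stood apart from those numbered 2 and 3 in all 4 groups. Antiviral genes, induced by interferons in most cells, had a median level of 9.35 in siCon replicate 1 against 7.45 and 7.39 in replicates 2 and 3. The interferon-inducible GTPases had medians of 10.01, 8.33 and 8.12. Higher levels were not confined to interferon genes. Median differences of siCon replicate 1 from the mean of numbers 2 and 3 were 1.63 for chemokines and 0.96 for immediate-early genes. They were 0.81 for cytokines and effectors, 0.68 for NF-κB targets and 0.37 for stress response genes. Against the mean of numbers 2 and 3, siCon replicate 1 was higher over the 16 microglia markers (median difference 0.71) and lower over the 13 meningeal and vascular markers (-1.20), the 17 cell cycle genes (-1.09) and the 15 ribosomal protein genes (-0.37). It was also lower over the 14 astrocyte markers (-0.23); each of these lists passed by fry, and 4192 genes differed in all by limma. These tests set 1 array against 2, take the spread only from numbers 2 and 3 of each group, and assume that the lone array varies like them. Interferon genes also rose less in number 1 with interferon-γ: the difference in the change, of 1 array per group in number 1, was -2.18 for the GTPases and -1.41 for the antiviral genes. For this reason, each comparison is given over all 12 arrays, with replicate number as a block where that changes a call, and without replicate 1.

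**Figure D1:**
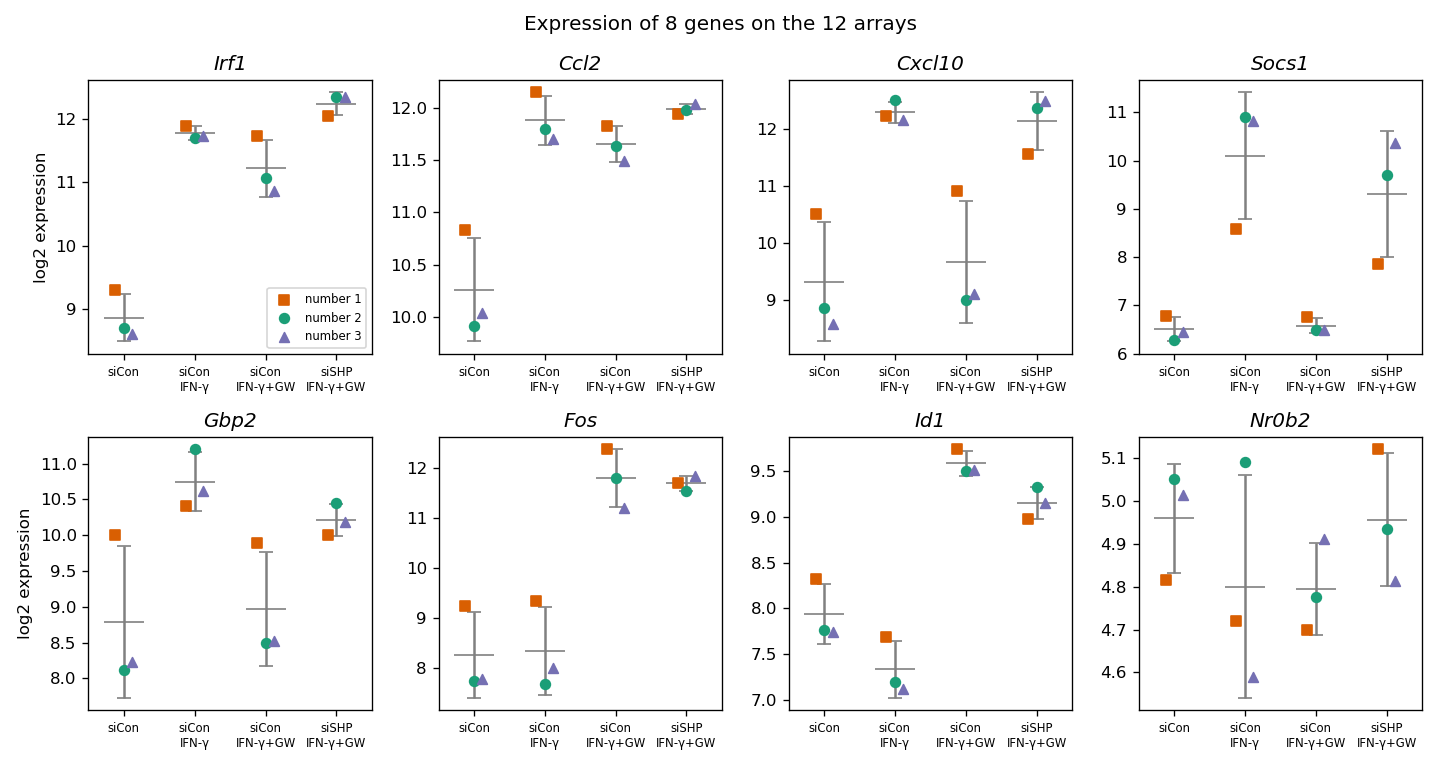
Log2 expression of 8 genes on each of the 12 arrays, by group on the horizontal axis; squares, circles and triangles are arrays numbered 1, 2 and 3, and grey bars are the mean ± SD of 3 arrays. Cxcl10 lay at 12.15 to 12.50 with interferon-γ and at 9.01 and 9.11 in numbers 2 and 3 with interferon-γ and GW, while number 1 reached 10.91 there. In siCon it lay at 10.52 in number 1 and at 8.86 and 8.59 in numbers 2 and 3.

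The comparison of siCon_IFNg with siCon asks which genes interferon-γ changed in these cultures. Irf1, a transcription factor induced early by interferon-γ, rose 7.49-fold (log2 2.91, SE 0.23, n = 3 arrays per group, limma adjusted p = 7.06e-04) from 8.87 ± 0.38 to 11.77 ± 0.11 (SD). Ccl2, a chemokine for monocytes, rose by 1.62 ± 0.21 (SE; adjusted p = 0.025), and the cytokine Il15 by 1.51 ± 0.21 (adjusted p = 0.025). The costimulatory receptor Cd40 rose by 1.27 and Socs2, a feedback inhibitor of cytokine receptors, by 1.54. In all, 22 genes changed, 15 higher and 7 lower. Other rises were those of Themis2 (2.20), C11h3orf38 (2.84-fold), Noct (1.46), Prkaa2 (1.34) and Hivep1 (1.25). The 7 that fell were Gadd45a, a growth arrest gene (-1.02), Arl11 (-0.96), Gpr34 (-0.89), Cdca7 (-0.84), Nim1k (-0.82), Bambi, a pseudoreceptor of the TGF-β family (-0.68), and Fnip2 (-0.64).

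The interferon signalling genes rose as a group. Over the 17 measured members the median change was 1.05, 16 were positive, and the list passed (fry adjusted p = 0.018; adjusted p = 0.047 by camera with an estimated correlation, and 0.094 by the latter with the block). Irf1 passed over all genes (6 members with the block), and 9 members passed when adjusted over the list alone. The 11 interferon-inducible GTPases had a median of 1.95 with 11 positive, yet 0 passed over all genes (2 with the block) and 7 adjusted over the list alone (fry adjusted p = 0.21; 0.058 with the block). The 31 antiviral genes had a median of 1.12, with 0 members past the threshold over all genes (4 with the block), 3 adjusted over the list alone and a fry adjusted p of 0.40. Of the 24 antigen presentation genes, whose median was 0.11, 0 passed in either way (fry adjusted p = 0.68). Without replicate 1, 14 of the signalling genes, 11 of the GTPases, 27 of the antiviral genes and 7 of the antigen presentation genes were higher by limma and 0 were lower. By camera with an estimated correlation these lists did not pass there (adjusted p = 0.064, 0.071, 0.071 and 0.19). There Cxcl9 differed by 6.50, Cd274, a ligand of an inhibitory T cell receptor, by 5.11, the signalling inhibitor Socs1 by 4.49, Cxcl10 by 3.60 and the GTPase Gbp2 by 2.73.

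Over all 12 arrays those genes had large changes that varied with the replicate number. Cxcl9, a chemokine for activated T cells, differed by 5.19 ± 0.87 (SE; limma adjusted p = 0.069; 0.024 with the block), Socs1 by 3.59 ± 0.66 (adjusted p = 0.098; 0.017 with the block) and Cxcl10 by 2.97 ± 0.56 (adjusted p = 0.11; 0.025 with the block). Gbp2 differed by 1.96 ± 0.50 (adjusted p = 0.33) and Nos2, the inducible nitric oxide synthase, was at least 2.82-fold higher, from background (adjusted p = 0.66), most of it in number 1 (log2 2.63; 0.93 and adjusted p = 0.0038 without replicate 1). Of the 18 chemokines Ccl2 passed over all genes and 7 adjusted over the list alone, and of the 29 cytokines and effectors 2 and 5. With the block 6 of each list passed over all genes, all higher. Both lists changed in either direction (fry mixed adjusted p = 0.0029 and 0.005), and with the block both rose (fry adjusted p = 0.031 and 0.018; by camera with an estimated correlation adjusted p = 0.094 and 0.048). Their medians of 0.85 and 0.82 came mostly from number 1 (1.62 and 1.37), and without replicate 1 they were 0.10 (7 higher, 2 lower) and 0.58 (14 higher).

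The other lists did not pass by fry in this comparison over all 12 arrays, and 0 of their members passed over all genes. Adjusted over the list alone, 2 immediate-early genes, 1 nuclear receptor and 1 meningeal or vascular marker passed. With the block 4 NF-κB targets, 2 immediate-early genes, 1 LXR target and 3 nuclear receptors and corepressors (1 higher, 2 lower) passed over all genes. Median changes were 0.64 for 15 NF-κB targets and feedback genes (1.75 in number 1, and 0.11 without replicate 1), 0.29 for 18 immediate-early genes (0.77 in number 1, and -0.00 without replicate 1), 0.10 for 15 stress response genes and -0.21 for 17 cell cycle genes. They were -0.07 for 19 LXR targets, -0.01 for 11 FXR targets, -0.09 for 16 PPAR targets, -0.06 for 15 cholesterol synthesis genes and -0.07 for 24 nuclear receptors and corepressors. Marker medians were -0.01 for astrocytes, -0.13 for microglia, -0.12 for 13 oligodendrocyte genes, 0.06 for 14 neuron genes and -0.07 for meningeal and vascular cells, and the ribosomal protein genes had -0.06. The astrocyte gene Gfap was at 11.91 ± 0.16 in siCon and 11.92 ± 0.17 in siCon_IFNg. With the block the neuron markers passed (fry adjusted p = 0.021; adjusted p = 0.15 by camera with an estimated correlation), where Tubb3 had at least 1.31 ± 0.44, from background (SE; limma adjusted p = 0.63). The count of changed genes was 170 with the block, with all 22 among them, and 856 without replicate 1 (554 higher, 302 lower). It was 2 or 3 without any of the 4 arrays numbered 2 or 3, and 66 without siCon_IFNg replicate 1.

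The comparison of siCon_IFNg_GW with siCon_IFNg asks what GW changed in the presence of interferon-γ. Genes of the immediate-early response, which cells switch on within minutes of a stimulus, rose. Fos rose by log2 3.46 (SE 0.48, n = 3 per group, limma adjusted p = 0.013), from 8.34 ± 0.88 to 11.79 ± 0.58 (SD). Klf2 rose by 2.38 ± 0.39 (SE; adjusted p = 0.023), Atf3 by 1.49 ± 0.18 (adjusted p = 0.0077), Jun by 1.45 ± 0.19 (adjusted p = 0.0086) and Klf4 by 1.63 (adjusted p = 0.036). All 18 members were positive with a median of 2.03; 5 passed over all genes and 17 adjusted over the list alone. The list passed the directional test (fry adjusted p = 0.032; 0.0039 with the block), but not by camera with an estimated correlation (adjusted p = 0.20). In pairs numbered 1, 2 and 3 the median changes were 1.92, 2.46 and 1.83. With the block 17 members were higher, and without replicate 1 all 18 were.

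In all, 161 genes changed with GW, 115 higher and 46 lower. The largest rises beside Fos were those of the Notch target Hes1 (2.90), the matricellular protein gene Ccn1 (2.75), H1f6 (2.65), the growth factor Hbegf (2.48), Klf2 and Id1, a BMP-responsive inhibitor of differentiation factors (2.26 ± 0.19 SE, limma adjusted p = 0.0018). Garin4 (at least 2.18, from background), the clock and stress repressor Bhlhe40 (2.08) and the adhesion molecule Flrt3 (2.02) followed. Of the 15 stress response genes 3 rose: Chac1 (1.42), the p53 target Mdm2 (0.73) and the heat shock gene Hsph1 (1.24), while Gclm, of glutathione synthesis, had -0.67 (adjusted p = 0.12; 0.012 with the block). Over that list 6 members passed adjusted over the list alone, 7 with the block over all genes, and the median was 0.30 (fry adjusted p = 0.076; 0.022 with the block, but 0.26 by camera with an estimated correlation). Insig1, which restrains sterol synthesis, rose by 1.19 ± 0.21 and Srebf1, a regulator of lipid synthesis genes and an LXR target, by 0.82 ± 0.15 (SE; limma adjusted p = 0.034 and 0.032). The cholesterol exporter Abca1 had 0.67 ± 0.21 (adjusted p = 0.21; 0.024 with the block). For the 19 LXR targets the median was -0.04 and the mean 0.08, with 1 member past the threshold either way (fry adjusted p = 0.23) and 5 with the block (4 higher, 1 lower).

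Genes with the largest falls under GW included several that interferon-γ raised. Cxcl9 fell at least 44.2-fold (log2 -5.47, SE 0.87, n = 3 per group, limma adjusted p = 0.019), from 11.15 ± 1.36 to 5.68 ± 0.92 (SD). Socs1 fell 11.5-fold (-3.52 ± 0.66 SE, adjusted p = 0.038) and Tnfsf10, a death receptor ligand, at least 6.94-fold (-2.79 ± 0.55, adjusted p = 0.046). The falls of Cxcl9, Tnfsf10 and Il15 are lower bounds, as their values with GW in numbers 2 and 3 lay under the 95th percentile of background genes (5.34). Falls of Themis2 (-2.10), Clec2g (-1.95), Apol3l1 (-1.71), Il15 (-1.69), the antiviral gene Zc3hav1 (-1.38), the cytokine receptor Lifr (-1.29) and C11h3orf38 (-1.24) followed. The immunoproteasome subunit Psmb10 (-1.08) and Cd40 (-0.81) also fell. Of the 15 genes raised by interferon-γ, 5 fell with GW, 1 rose, and 4 of the 7 it lowered rose. With the block 54 of 108 fell and 6 rose. The comparisons share the siCon_IFNg arrays with opposite sign, which can alone give overlap, and no overlap expected from sharing was computed.

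Most interferon genes passed this comparison with the block or without replicate 1, but not over all 12 arrays. Over all genes and adjusted over the list alone, falls passed for 1 and 7 of 17 signalling genes, 0 and 7 of 11 GTPases, 0 and 7 of 31 antiviral genes and 1 and 6 of 24 antigen presentation genes. Median changes were -0.80, -1.88, -1.31 and -0.37. Their fry adjusted p was 0.076, 0.076, 0.16 and 0.16, and with the block each list fell (fry adjusted p = 0.038), although not by camera with an estimated correlation (adjusted p = 0.26). With the block 5 signalling genes, 10 GTPases, 20 antiviral genes and 8 antigen presentation genes were lower, and without replicate 1 the numbers were 13, 11, 28 and 13 (adjusted p = 0.13 for each list with an estimated correlation). Cxcl10 had -2.62 ± 0.56 (SE; limma adjusted p = 0.067; 0.017 with the block), Gbp7 -2.91 ± 0.59 (adjusted p = 0.055; 0.0185 with the block) and Gbp2 -1.78 ± 0.50 (adjusted p = 0.16; 0.043 with the block). Without replicate 1 they had -3.27, -3.68 and -2.40. In pairs numbered 1, 2 and 3 the GTPase medians were -0.55, -2.97 and -2.41. The difference between number 1, with 1 array per group, and the others had a median of 2.32 for the GTPases and 1.42 for the antiviral genes. In siCon_IFNg_GW against siCon, pairs 1, 2 and 3 had medians of -0.14, -0.38 and -0.08 for the GTPases. For the antiviral genes they were -0.16, -0.38 and -0.11. Median levels with GW thus lay near or under those of siCon of the same number in each pair.

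Irf1 and Ccl2 did not pass with GW. Irf1 had -0.55 ± 0.23 (SE; limma adjusted p = 0.37; -0.74 and 0.0019 without replicate 1) and Ccl2 -0.23 ± 0.21 (adjusted p = 0.80). The 18 chemokines and the 29 cytokines and effectors changed in either direction (fry mixed adjusted p = 0.0084 for both) with medians of -0.11 and -0.32. Of them 1 and 3 passed over all genes, all lower, and 5 and 4 adjusted over the list alone. With the block 6 chemokines (1 higher, 5 lower) and 7 cytokines and effectors (2 higher, 5 lower) passed over all genes. With the block the cytokine list fell (fry adjusted p = 0.047; adjusted p = 0.26 by camera with an estimated correlation).

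Microglia markers were lower in the GW arrays. The median over 16 was -0.44 and 15 were negative (fry adjusted p = 0.076; mixed adjusted p = 0.019), with 0 past the threshold over all genes and 2 adjusted over the list alone. With the block 10 fell and the list passed (fry adjusted p = 0.030; adjusted p = 0.26 by camera with an estimated correlation); Tyrobp had -0.84 (limma adjusted p = 0.058; 0.024 with the block) and C1qb, of the complement cascade, -0.56 (adjusted p = 0.11; 0.015 with the block). In pairs 1, 2 and 3 the medians were -0.51, -0.47 and -0.41. The lists that did not pass by fry over all 12 arrays also included NF-κB targets (median 0.43), FXR targets (0.00), PPAR targets (-0.09), cholesterol synthesis (0.02), nuclear receptors and corepressors (0.01), cell cycle (0.04), astrocyte markers (-0.01), oligodendrocyte markers (-0.01), neuron markers (-0.12), meningeal and vascular markers (-0.04) and ribosomal protein genes (-0.12). With the block, fry passed for PPAR targets, cholesterol synthesis and ribosomal protein genes (adjusted p = 0.038 each) and for neuron markers (adjusted p = 0.0097). With the block 3 NF-κB targets rose, and 2 PPAR targets (1 higher, 1 lower), 2 cholesterol synthesis genes (both higher), 2 nuclear receptors and corepressors (1 higher, 1 lower), 1 cell cycle gene (higher) and 1 astrocyte marker (lower) passed over all genes. By camera with an estimated correlation the lists passed by fry had adjusted p = 0.30, 0.38, 0.30 and 0.26. The count of changed genes was 1189 with the block, all 161 among them, and 2081 without replicate 1 (1176 higher, 905 lower). It lay between 27 and 51 without any of the 4 arrays numbered 2 or 3 and was 412 without siCon_IFNg replicate 1 and 106 without siCon_IFNg_GW replicate 1.

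The siRNA target came first in the comparison of siSHP_IFNg_GW with siCon_IFNg_GW. Nr0b2 was not lower in the arrays labelled SHP siRNA: it measured 5.12, 4.94 and 4.81 there and 4.70, 4.78 and 4.91 in siCon_IFNg_GW, a difference of 0.16 ± 0.14 (SE, n = 3 per group, limma adjusted p = 1). It was at 4.82, 5.05 and 5.01 in siCon and at 4.72, 5.09 and 4.59 in siCon_IFNg. These levels lie near the background: 10.1% of 1344 olfactory and vomeronasal receptor genes, which astrocytes are not known to use, had a higher mean than the 4.88 of Nr0b2. At that level the array neither shows nor excludes a knockdown, and the group is named by its label throughout. Ptpn6 and Ptpn11, phosphatases that have also been called SHP, were chosen after the data were seen. They measured 8.62 ± 0.28 and 9.48 ± 0.03 (SD) against 8.51 ± 0.42 and 9.47 ± 0.18.

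Over all 12 arrays 0 genes passed between the arrays labelled SHP siRNA and siCon_IFNg_GW by limma, 416 had an unadjusted p under 0.05, and the block gave 0 (972 unadjusted; smallest adjusted p 0.062). Array weights gave 127 genes, 122 of them higher. The genes with the smallest p, which did not pass, included interferon genes with higher values. Cxcl9 differed by at least 5.16 ± 0.87 (SE), from 5.68 ± 0.92 to 10.84 ± 1.57 (SD), Cxcl10 by 2.46 ± 0.56, Themis2 by 1.48 ± 0.31, Irf1 by 1.02 ± 0.23 and Cd40 by 0.69 ± 0.16 (limma adjusted p = 1 for each). Others were Tifa, an adaptor of NF-κB signalling (0.82), Hivep1 (0.43) and Ddhd1 (0.41). Fbxo39 and Npy4r were also among them, with both group means under the background percentile of 5.34, so their differences are not read. With the block the adjusted p of these genes lay between 0.44 and 0.51. Socs1 had 2.73 ± 0.66, Gbp2 1.24 ± 0.50, Nos2 at least 1.19 ± 0.52, from background, and Ccl2 0.33 ± 0.21. Abca1 (-0.11), Srebf1 (0.13) and Gfap (-0.02) lay within 1 SE of 0.

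Without replicate 1, 267 genes passed, 246 higher and 21 lower. Among the higher genes there were all 11 GTPases, 25 of 31 antiviral genes, 10 of 17 signalling genes and 6 of 24 antigen presentation genes. Cxcl9 differed by at least 6.60 there (limma adjusted p = 6.51e-06), from values under the background percentile, Cxcl10 by 3.36, Socs1 by 3.54, Irf8, a transcription factor of interferon responses, by 3.46 and Irf1 by 1.37. The first 3 of these lists held with an estimated correlation (camera adjusted p = 0.047 each), and antigen presentation did not (adjusted p = 0.11). Of those 246 genes, 221 were also lowered by GW without replicate 1; both comparisons share the siCon_IFNg_GW arrays with opposite sign, which can alone give overlap. In number 1 the list medians were 0.10 for the GTPases and -0.04 for the antiviral genes, against 1.95 and 1.91, and 1.52 and 1.63, in numbers 2 and 3.

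No list passed over all 12 arrays or with the block in this comparison; the smallest fry adjusted p was 0.34 over all arrays, for the signalling genes (median 0.71, 0 members past the threshold over all genes and 6 adjusted over the list alone). Medians were 1.33 for the GTPases (5 adjusted over the list alone), 1.11 for antiviral genes, 0.15 for antigen presentation, 0.03 for chemokines (4 adjusted over the list alone) and 0.26 for cytokines and effectors (1). They were 0.12 for NF-κB targets, -0.18 for immediate-early genes, -0.06 for stress response, -0.05 for PPAR targets and cholesterol synthesis, -0.04 for FXR targets, 0.07 for cell cycle and 0.09 for microglia markers. LXR targets had -0.00, nuclear receptors and corepressors -0.04, and the markers of astrocytes 0.01, oligodendrocytes -0.01, neurons 0.03 and meningeal and vascular cells 0.07. Ribosomal protein genes had 0.03. Across the 3 comparisons, camera with a preset correlation of 0.01 called 9, 10 and 6 of the 21 lists, of which 1, 0 and 0 held with an estimated correlation.

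**Figure D2:**
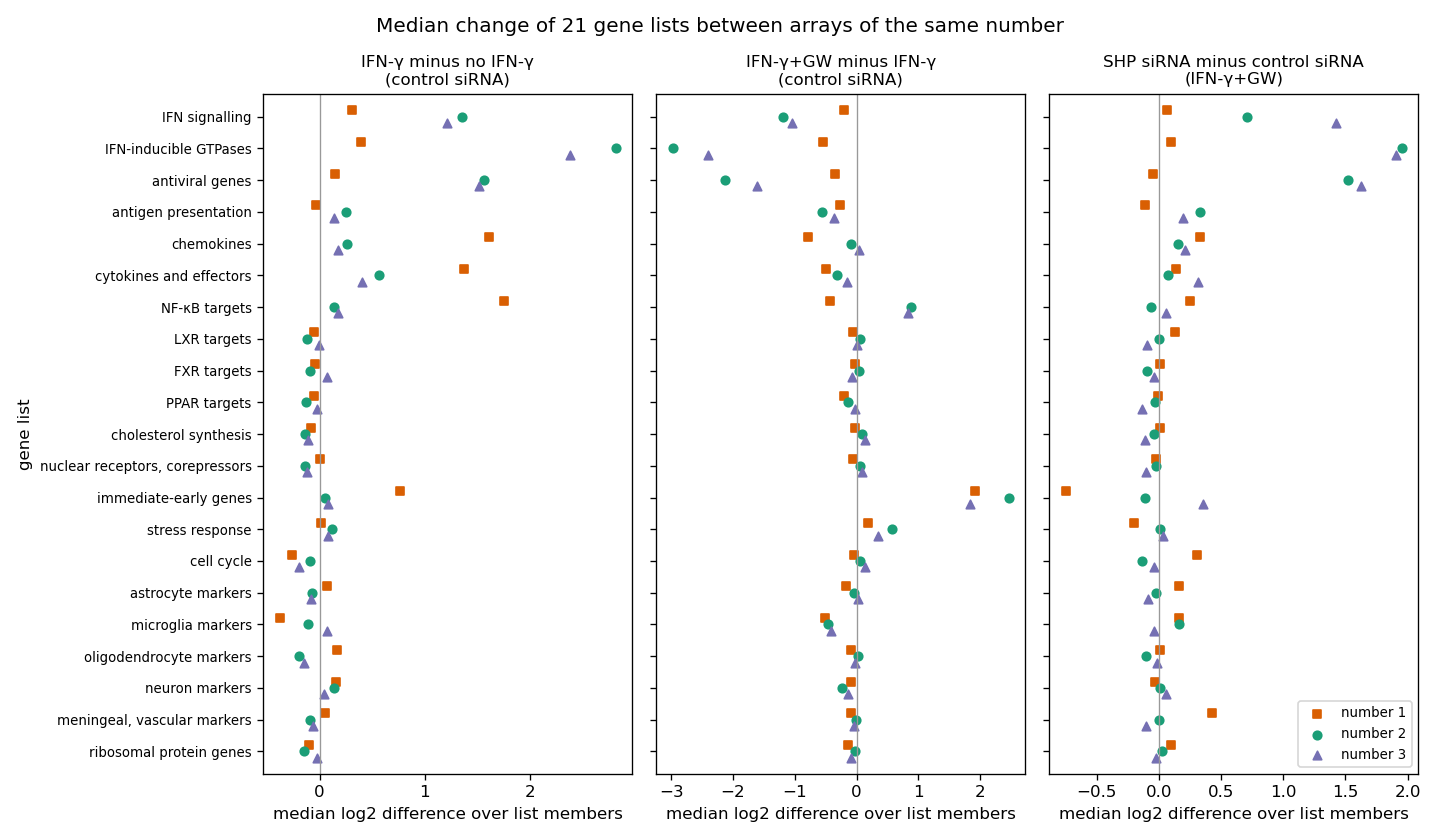
Median log2 difference over the measured members of each of 21 gene lists (vertical axis), between arrays of the same number, for 3 comparisons; squares, circles and triangles are numbers 1, 2 and 3, and the horizontal scales differ. Immediate-early genes were higher with GW in each number (1.92, 2.46 and 1.83), while the GTPases fell by 0.55 in number 1 and by 2.97 and 2.41 in numbers 2 and 3.

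A further question was whether GW and the siRNA moved the genes that interferon-γ had raised. The 15 genes raised in siCon_IFNg share no array with the siRNA comparison. Their median change in the arrays labelled SHP siRNA was 0.39 and 14 were positive (fry p = 0.0023, camera with an estimated correlation p = 8.96e-04). In pairs 1, 2 and 3 the medians were 0.17, 0.49 and 0.60. An exact permutation test of the array medians gave p = 0.10, the smallest that 3 against 3 arrays allow (two-sided). With the block 108 genes had a median of 0.40, and without replicate 1, 554 genes had 0.45. Without replicate 2 or without replicate 3 too few genes were raised to form a set.

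For GW, the set fixed before the data were examined was the 120 genes higher in siSHP_IFNg_GW than in siCon, which share no array with the GW comparison. Their median change with GW was 0.64 and 97 were positive (fry p = 9.05e-05, camera with an estimated correlation p = 0.0044; exact permutation p = 0.10). With the block 600 genes had a median of 0.36, and without replicate 1, 1022 genes had 0.18 and the call was lost by fry and by camera. Both groups that define this set differ in GW as well as in interferon-γ, so it also takes in genes that GW raised, such as Fos, Ccn1 and Id1. It therefore does not isolate interferon genes. The 2 members on the 4 interferon lists had -0.68. The 15 genes chosen by siCon_IFNg against siCon had a median of -0.54 with 13 negative. They share arrays with the GW comparison, and 100 simulations without a GW effect gave a mean median of -0.08 and a lowest of -0.21. The simulations drew the noise of each gene independently and called 30 genes on average. They cannot say how far the median of 15 genes that vary together strays by chance. In a choice made after seeing the data, the 100 genes with the largest interferon-γ rise in number 2 had a median of -1.86 with GW in number 3, and 97 were negative. The reverse choice gave -2.11 and 93 negative. The same genes had medians of -0.28 and -0.32 in number 1, with 76 of 100 negative each time. The 100 genes chosen in number 1 went the other way, with medians of 0.67 and 0.52 in numbers 2 and 3 and 24 and 26 negative. Their interferon-γ medians in numbers 2 and 3 were only 0.33 and 0.28. Genes chosen in numbers 2 and 3 had interferon-γ medians of 2.07 and 2.20 in the other of these numbers, and 0.24 and 0.28 in number 1. In the siRNA comparison the genes chosen in number 2 or 3 had medians of 1.75 and 1.58 in the other of these numbers, with 100 of 100 positive, and 0.02 in number 1, with 54 positive. Those chosen in number 1 had -0.04 and 0.17, with 46 and 66 positive.

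Changes with GW and in the arrays labelled SHP siRNA were negatively correlated across genes. Pearson's r over 18166 genes, which are not independent replicates, was -0.61 and Spearman's rho -0.44. The shared siCon_IFNg_GW arrays alone gave r = -0.50 in simulations, with a lowest of -0.54. These drew each gene independently and without replicate effects, while members of a list were correlated (0.67 for the antiviral genes). How far r and the covariance stray by chance is therefore not known from them. The covariance was -0.034 against a simulated -0.011. Fold changes from different replicate numbers, which share no array, gave a mean r of -0.20 over 6 combinations (-0.47 to -0.02). Between numbers 2 and 3 alone r was -0.47 and -0.42. For interferon-γ and GW r was -0.47 against a simulated -0.50, and the covariance -0.035 against a simulated -0.011. Across numbers the mean r was -0.14 (-0.45 to 0.11), with -0.45 for both combinations of numbers 2 and 3.

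The remaining comparisons differ by both treatments or both factors. In siCon_IFNg_GW against siCon, 157 genes differed, 106 higher and 51 lower. Irf1 (2.35 ± 0.23 SE, limma adjusted p = 0.0017) and Ccl2 (1.39 ± 0.21, adjusted p = 0.017) were higher, as were Ccn1 (3.98), Fos (3.54), Hbegf (2.41) and Jun (2.40). Gpr34 (-1.10) and Tyrobp (-0.92), both known from microglia, and Arl11 (-0.88) were lower. The 16 microglia markers had a median of -0.57 and all were negative (fry adjusted p = 0.041, and adjusted p = 0.21 by camera with an estimated correlation). Immediate-early genes (median 2.46, fry adjusted p = 0.0073) and stress response genes (median 0.43, fry adjusted p = 0.029) also passed. By camera with an estimated correlation both had an adjusted p of 0.15. Cxcl10 (0.35 ± 0.56), Socs1 (0.07 ± 0.66), Gbp2 (0.18 ± 0.50) and Cxcl9 (-0.28 ± 0.87) did not pass. Of the 15 genes raised by interferon-γ alone, 7 were also higher here. The block gave 1242 genes (534 higher, 708 lower), 1028 passed without replicate 1, and counts without 1 array were 23 to 81.

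In the arrays labelled SHP siRNA against siCon_IFNg, 55 genes differed, 44 higher and 11 lower. Fos (3.35), Ccn1 (2.71), H1f6 (2.71), Hbegf (1.97), Id1 (1.82) and Jun (1.49) were higher, and Il15 was lower (-1.36 ± 0.21 SE, limma adjusted p = 0.039). Cxcl10 (-0.16 ± 0.56), Cxcl9 (-0.31 ± 0.87), Gbp2 (-0.53 ± 0.50) and Irf1 (0.47 ± 0.23) did not pass. Socs1 had -0.79 ± 0.66 (adjusted p = 0.85; 0.045 without replicate 1). The block gave 559 genes (354 higher, 205 lower) and 1129 passed without replicate 1. Counts without 1 array went from 0, without replicate 3 of either group, to 155 without siCon_IFNg replicate 1.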

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

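Rows without a gene name lay outside the comparisons of the report, and 14 of 17599 changed with GW under interferon-γ in the fit over all rows (limma, 9 higher and 5 lower), against 0 with interferon-γ alone and 0 in the arrays labelled SHP siRNA. In those comparisons 2 and 0 of all rows passed. The rises included those of rows 17881529 (2.75 ± 0.41 SE, from a mean of 4.10 to 6.85, adjusted p = 0.034) and 17719474 (2.18 ± 0.28, from 5.66 to 7.83, adjusted p = 0.021). The falls included those of rows 17883179 (-1.46 ± 0.21, from 5.75 to 4.29, adjusted p = 0.032) and 17769169 (-1.29 ± 0.20, from 5.49 to 4.20, adjusted p = 0.035). Values under the background percentile of 5.34 make the changes of the 1st, 3rd and 4th of these lower bounds. These rows were not tied to a gene here, and no explanation was tested.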

How the results depend on the processing

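Counts of changed genes depended on how the arrays numbered 1 were treated and on further choices. Over all 12 arrays 22 genes changed with interferon-γ, 161 with GW, 0 in the arrays labelled SHP siRNA, 55 for those arrays against siCon_IFNg and 157 with both treatments. With the replicate block there were 170, 1189, 0, 559 and 1242, and with a random replicate block 94, 716, 0, 287 and 711. Array weights gave 414, 1307, 127, 594 and 1282. A batch block for number 1, chosen after seeing the data, gave 232, 1558, 1, 795 and 1604. Fits of only the 6 arrays compared gave 7, 4, 0, 6 and 32, with fewer arrays to estimate the spread, and an adjusted p under 0.10 gave 43, 283, 0, 128 and 297. Over all rows, with more tests, there were 2, 83, 0, 11 and 94. Centring gave 15 (12 higher and 3 lower against 15 and 7), 79, 0, 30 and 79, and without the dimmest 33.3% of genes 96 differed between siSHP_IFNg_GW and siCon_IFNg. Leaving out arrays or a replicate number gave 0 to 856 for interferon-γ, 0 to 2081 for GW, 0 to 267 for the siRNA, 0 to 1129 for siSHP_IFNg_GW against siCon_IFNg and 0 to 1028 for both treatments; the highest came without replicate 1 each time. Each such fit pools the spread over groups. Except where the number of arrays or tests shows it, the cause was not tested. Quantile normalization, the mean of a gene's rows, trend and robust settings and the 1.5-fold threshold kept each count within 1.5 times.

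The median change with GW over the genes higher in siSHP_IFNg_GW than in siCon was 0.64. It kept its sign except over the 2 members of the interferon lists, where it was -0.68, and the cause was not tested. Too few genes were chosen to test this change without replicate 2 or without replicate 3. Without replicate 1 the median was 0.18 and no longer passed by fry, and the cause was not tested. The change of the genes raised by interferon-γ in the arrays labelled SHP siRNA kept its call under the 7 alternatives that gave a set (0.39 to 0.45). Without replicate 2, without replicate 3, or with members of the interferon lists alone, too few genes were chosen to test. The correlation between the changes with GW and the siRNA was -0.61, between -0.64 and -0.51 when a replicate number was left out, and -0.20 across numbers, where no arrays are shared. Sharing of arrays alone gave -0.50 in simulations of independent genes, so the values with shared arrays do not by themselves show a relation. Lists past the threshold by fry numbered 1, 1 and 0 for interferon-γ, GW and the siRNA; with the block 4, 12 and 0, without replicate 1 11, 12 and 7, with quantile normalization 1, 3 and 0, and by camera with an estimated correlation 1, 0 and 0. The cause was not tested.

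For single named genes, 502 values kept their status, called or not called, 136 were weaker, 10 stronger and 0 reversed. Those of the siRNA comparison, where 0 genes passed, had no call to keep. Leaving out all arrays numbered 1 was not among these settings. Without replicate 1 the fry direction turned for chemokines with GW (up, median -0.02, fry adjusted p = 0.0046; adjusted p = 0.91 by camera with an estimated correlation) and for nuclear receptors with the siRNA (down, median -0.08, fry adjusted p = 0.035; adjusted p = 0.57 with an estimated correlation), neither of which had passed over all arrays; the cause was not tested. Genes near the background, Nr0b2 among them, could not show a fall.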

Other observations

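All tests of explanations below were chosen after the results were seen, as were the comparison of number 1 with numbers 2 and 3 and the values without replicate 1 for lists.

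Targets and feedback genes of NF-κB, the transcription factor of inflammatory signals, had median changes that differed between replicate numbers with interferon-γ and with GW. Both comparisons hold siCon_IFNg replicate 1, with opposite sign, so the 2 differences are not separate findings. With interferon-γ their median change was 1.75 in number 1 and 0.14 and 0.17 in numbers 2 and 3, and the difference passed (median 1.26, fry adjusted p = 5.42e-04; 13 of 15 members by limma). This test has 1 array per group in number 1 and assumes that it varies like numbers 2 and 3, which alone give the spread. With GW the median change was -0.43 in number 1 and 0.88 and 0.84 in numbers 2 and 3 (difference -1.40). Against the mean of numbers 2 and 3, the list was higher by a median of 1.94 in siCon_IFNg replicate 1. The same difference was 0.68 in siCon, 0.74 in siCon_IFNg_GW and 1.05 in siSHP_IFNg_GW. In siCon_IFNg_GW against siCon, which leaves out the siCon_IFNg arrays, the medians were 1.22, 1.07 and 1.10 in pairs 1, 2 and 3. A reversal with GW in number 1 is therefore not shown apart from that array. Without replicate 1, 12 of the 15 rose with GW, among them the inhibitor gene Nfkbia (2.04), Nfkbiz (2.34) and the survival gene Ier3 (2.18). The list passed there by fry (adjusted p = 2.13e-04) but not by camera with an estimated correlation (adjusted p = 0.13). Over all 12 arrays limma gave these 3 genes an adjusted p of 0.36, 0.53 and 0.36, and with the block 0.038, 0.026 and 0.016. Without replicate 1, 6 of the 18 chemokines rose with GW and 6 fell. Cxcl1 (3.32), Cxcl2 (3.77), Ccl3 (4.24) and Ccl4 (3.55) were among the higher ones. Cxcl9 (-6.77, a bound set by background), Cxcl11 (-4.70) and Cxcl10 (-3.27) were among the lower ones. The other chemokines that passed are not listed, and no division by the cells they attract was tested. With the block Cxcl1 (adjusted p = 0.035), Cxcl9 (0.0073), Cxcl11 (0.027) and Cxcl10 (0.017) passed by limma, and Cxcl2, Ccl3 and Ccl4 did not (0.13, 0.086 and 0.11).

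Among nuclear receptor genes, the circadian repressor Nr1d1 had 1.63 ± 0.77 (SE) with GW (limma adjusted p = 0.47 over all arrays, 0.0011 with the block), and pairs 1, 2 and 3 gave 1.15, 1.76 and 1.97. Its mean was 9.34 in siCon, 8.30 in siCon_IFNg and 9.92 in siCon_IFNg_GW, so the rise started from a level under that of siCon. Ppard, of the PPAR family, had 0.96 ± 0.19 with interferon-γ (adjusted p = 0.12; 0.030 with the block) and -0.76 ± 0.19 with GW (adjusted p = 0.11; 0.029 with the block). Among immediate-early genes Nr4a1 had 4.11 with GW (adjusted p = 0.11; 9.87e-04 with the block).

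Real splits of the 6 arrays gave 22 genes for interferon-γ, 161 for GW, 0 for the siRNA, 55 for the arrays labelled SHP siRNA against siCon_IFNg and 157 for both treatments. The highest of the other 9 splits was 0 each time. As many genes as in the real split came in 1 of 10 splits for 4 of these comparisons and in 10 of 10 for the siRNA. The 10 splits are too few for a share under 0.05. Among the 4 splits that part all pairs, the highest other count was also 0.

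Arrays numbered 1 had high interferon genes without added interferon-γ and a smaller rise with it. The shift in siCon replicate 1 was wider, with higher chemokines (median difference 1.63), immediate-early genes (0.96) and NF-κB targets (0.68). A larger share of microglia, counting only the transcripts of these cells themselves, is argued against as the sole source of the high interferon genes. The microglia marker that rose most in siCon replicate 1, Ly86, rose by 1.58, less than the median antiviral gene (2.14). This rests on 1 array and does not bear on what such cells may do to the astrocytes, which was not tested. The serum-free step was meant to remove microglia, though the median of their markers lay over background on all arrays. A swap of siCon and siCon_IFNg replicate 1 is argued against by Irf1, higher by 2.60 in siCon_IFNg, and compressed values by the NF-κB list, which rose more there (by 1.26, with 1 array per group). What remains open is a separate batch or preparation, since the 4 arrays deviated together (lowest correlation 0.63), which could also have differed in biology; cells already exposed to interferon are a possible explanation that was not tested. Beyond the share of microglia no biological explanation was tested, because no group of the design bears on it, and whether these are the 4 arrays taken from an earlier series is not known.

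Immediate-early genes were higher with GW in all 3 numbers. Handling of the siCon_IFNg or siCon_IFNg_GW dishes alone is argued against by siSHP_IFNg_GW against siCon, which share no array with the GW comparison: the median was 2.37 there and 18 of 18 genes were positive. An effect of the vehicle or of a medium change that came with GW cannot be told apart from one of GW itself (median 2.03), because no group received the vehicle alone. A response to the compound may be the source, and remains a hypothesis.

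Interferon genes such as Cxcl10 and Socs1 lay near control levels in siCon_IFNg_GW. Microglia markers were lower in the same comparison (median -0.44), and a part of these cells in the falls was not excluded. A loss of all induced transcripts is argued against by the immediate-early genes, whose median rose by 2.03. That rise does not bear on a wider loss that spared immediate-early genes, which was not tested. That interferon-γ did not act in those dishes stays open: 7 of the 15 genes it raised, among them Irf1 and Ccl2, were still higher than in siCon, but without a group given GW alone these may have been raised by GW. A lower response to interferon-γ in the presence of GW, partly lifted by the SHP siRNA in numbers 2 and 3, is a candidate explanation that Nr0b2, near background, could not test.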
